A study of Pseudomonas protegens with 6 samples.

How the data were processed

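Total RNA from wild-type Pseudomonas protegens H78 and from its crc deletion mutant, 3 libraries each, was the material. Per the labels' protocols, cells were grown at 28 °C in KMB medium, RNA was purified on columns with DNase treatment, ribosomal RNA was removed and cDNA was sequenced on a BGISEQ-500. The submitters' processing notes name Bowtie2, HISAT and RSEM, and their roles and versions, and the genome build, are not given in the sources used here. The deposited table gives per-library FPKM, which the authors computed, for 6290 genes, of which 6288 are coding sequences and 2 are RNA features. Per the file headers it also holds group means, a log2 ratio of means and a probability, whose method is not given in the sources used here. The authors' log2 ratio is that of their mean FPKM without a pseudocount (largest difference 1.1e-14). Gene names, products and coordinates were used as that table gives them. Reads shared between near-identical gene copies, and reads of overlapping genes, cannot be separated from FPKM, so values of genes with copies are uncertain. Nothing in the labels says that libraries of a strain came from separate cultures, so p-values measure the spread between libraries, which may be technical.

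A count test had been intended, but the values are FPKM, so limma was used instead, on log2(FPKM + 1), with trend and robust variance estimates. Genes with a mean below 1 FPKM were left out, which left 6288, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. All 6 libraries entered 1 fit with the strain as its term. Versions were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Test, thresholds, 40 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 4 measured members, 38 of them, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. A list takes genes whose symbol matches in full or whose product text holds a term, so some members do other things than the list's name says. The list meant for ribosomal and transfer RNA matched 9 RNA modification enzymes. The named genes are crc, the 10 largest changes each way among called genes with non-overlapping groups and at least 10 FPKM in a strain, and the 3 largest such changes per list. In a list with no called member the 2 most abundant members may be named. Not all genes the rule selects are described, and genes outside it are marked as chosen after their values were seen.

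Depth was estimated from FPKM, because low values times gene length, less 36 bases, are whole multiples of 1 step per library. Between 98.0% and 100% of the values up to 8 fragments lay within 0.1 of a whole number, against 31.1% to 39.7% after random rescaling. These estimates served to describe depth, and no test used them. On simulated data with 200 changed genes among 6288, limma called 8% of genes changed by 0.5 on the log2 scale. It called 50% of those changed by 1 and all of those changed by 2 or 3, and 3.73% of calls were false. That single simulation drew noise independently for each gene and library. In the real libraries 65.2% of the within-strain variance lay on 1 axis shared across genes, so these rates may not hold for them. Alternatives were pseudocounts of 0.1 and 10, no filter and a filter of 10 FPKM, stricter thresholds, the replicate number as a block and each library left out in turn. Further ones were added after seeing the data. The alternatives for read counts were not applicable, and a search for the Hfq and Crc binding motif was not run, since no genome sequence was used here.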

Results

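RNA was sequenced from Pseudomonas protegens H78, a plant-associated bacterium that makes antibiotics, and from a mutant of it lacking crc. The Crc protein acts with the RNA-binding protein Hfq to keep genes for less favoured carbon sources shut while better ones last. Both strains were harvested in late exponential growth at an optical density (OD600) between 4 and 5, and each is represented by 3 libraries. The table gives FPKM (fragments mapped to a gene, scaled by its length and by the fragments mapped in the library) for 6290 annotated genes in each library. The step between low FPKM values puts the depth, to the nearest 10000, at 6440000, 6300000 and 6530000 fragments in wild-type libraries 1 to 3. The same estimate gave 8080000, 5940000 and 6510000 fragments for mutant libraries 1 to 3. A single fragment in a gene of 1000 bases was worth 0.128 to 0.175 FPKM, so a gene of that length near 1 FPKM rests on few fragments. Spearman correlations across genes were 0.962 to 0.987 between libraries of a strain and 0.916 to 0.960 between strains. Within their strains, wild-type library 2 and mutant library 1 stood apart. The mean log2 level of the ribosomal protein genes was 10.02 in wild-type library 2, against 10.62 and 10.33 in the other wild-type libraries. It was 9.73 in mutant library 1, against 10.30 and 10.65 in the other mutant libraries.

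The deleted gene was examined first in every library. The crc gene (H78_06267, positions 6835818 to 6836597 on the plus strand of the authors' annotation) stood at 259, 320.0 and 245 FPKM in the wild-type libraries and at 1.16, 1.58 and 0.41 FPKM in the mutant libraries. The mutant values correspond to about 7, 7 and 2 fragments, so the transcript was nearly absent from every mutant library and the labels of all 6 libraries fit the crc values. The mean fell from 274 ± 40.03 to 1.05 ± 0.593 FPKM (SD, n = 3). In limma the log2 change was -7.10 ± 0.27 (SE), with an adjusted p of 1.12e-06, on a scale of FPKM plus 1 that understates changes of genes near 0. The neighbouring genes were not called. The pyrE gene stood at 154 ± 28.0 FPKM in wild type and 152 ± 50.7 FPKM in the mutant, and argB at 176 ± 3.71 and 196 ± 7.38 FPKM. Genes for Hfq and for the CbrA and CbrB regulatory system were not called either and were chosen after their values were seen. The hfq gene stood at 4146 ± 966 and 3463 ± 928 FPKM, and the 2 genes of the CbrA and CbrB regulatory system had log2 changes of 0.22 and 0.28.

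The comparison of the strains asks which transcripts differ when Crc is missing. Lists of arginine and proline catabolism, amino acid and peptide uptake and flagellar genes were higher in the mutant by camera (adjusted p = 9.88e-11, 2.82e-08 and 3.86e-13), and the pyoluteorin list was lower (adjusted p = 3.5e-13). With an estimated correlation camera called none of these lists (adjusted p = 0.268, 0.341, 0.264 and 0.341). The aroF_1 gene, for an enzyme of aromatic amino acid synthesis, rose 18.3-fold by mean FPKM, while the alcohol dehydrogenase gene pedE fell from 139 ± 69.3 to 5.86 ± 0.720 FPKM (SD, n = 3). Of 6288 genes tested with limma, 262 passed an adjusted p of 0.05, 141 of them higher and 121 lower in the mutant. An absolute log2 change of at least 1 was met by 126 of the higher and 105 of the lower genes. All 262 called genes had groups that did not overlap, a state reached by 1417 tested genes, or 22.5%, where chance gives 10%. Without mutant library 2, 111 genes passed (85 higher, 26 lower), and without wild-type library 3, 170 passed, 76 of them lower. Lower genes numbered 78 without mutant library 3 and 189 without mutant library 1, and leaving out wild-type library 2 and mutant library 1 together, a choice made after seeing the data, gave 828 genes (368 higher, 460 lower).

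**Figure D1:**
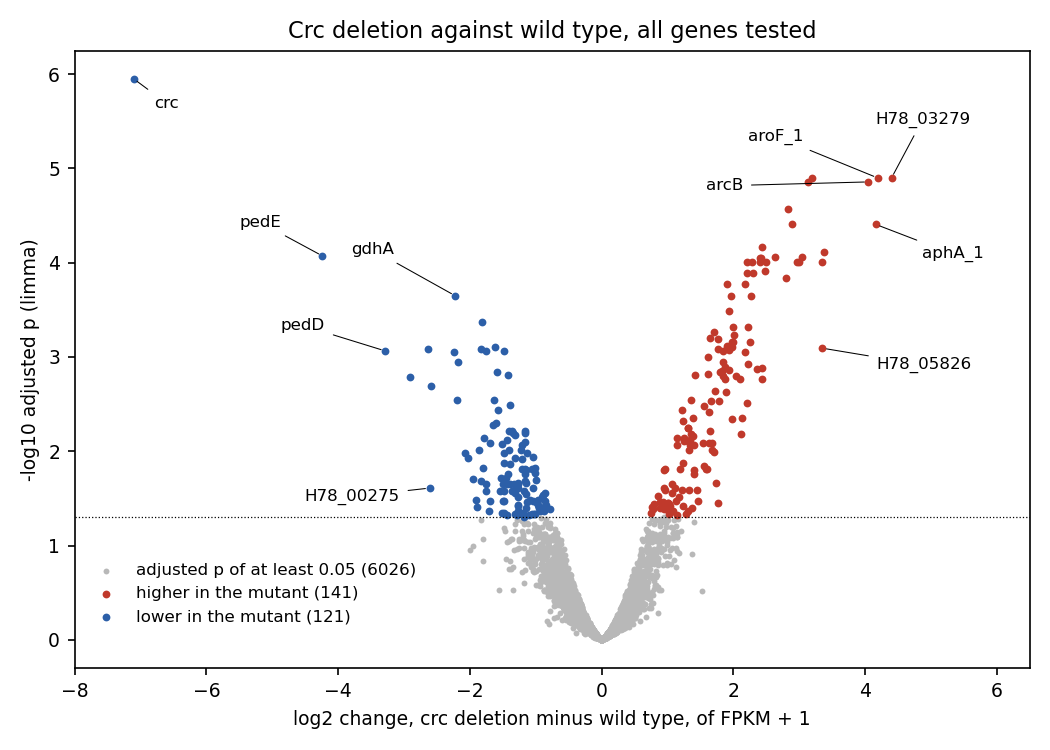
Log2 change of FPKM plus 1 (crc deletion minus wild type, horizontal axis) against -log10 of the limma adjusted p (vertical axis) for 6288 genes, 1 point each. Red points are the 141 genes higher in the mutant, blue points the 121 lower ones, and grey points genes that did not pass 0.05 (dotted line), with crc at the far left at -7.10.

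The gene with the largest rise was H78_03279, an amino acid ABC transporter substrate-binding protein, which went from 6.21 ± 1.1 to 152 ± 28.2 FPKM (SD, n = 3), a log2 change of 4.40 ± 0.24 (SE) with a limma adjusted p of 1.26e-05. The aroF_1 gene, for the aldolase that opens aromatic amino acid synthesis, rose from 74.5 ± 18.4 to 1363 ± 225 FPKM, a log2 change of 4.19. A pair of adjacent genes followed: aphA_1, annotated as an acetylpolyamine aminohydrolase, rose from 14.5 ± 3.70 to 284 ± 104 FPKM, and arcB, annotated as ornithine cyclodeaminase, which turns ornithine into proline, rose from 17.8 ± 3.19 to 314 ± 76.3 FPKM. A glutamate--ammonia ligase gene, H78_04797, rose from 76.3 ± 9.43 to 678 ± 72.2 FPKM, a log2 change of 3.14. The hypothetical gene H78_01420 was the most abundant of the 10 largest rises, at 589 ± 67.5 FPKM in wild type and 4852 ± 354 FPKM in the mutant. The others were the regulator H78_06257 (log2 change 3.38), the iron-dependent alcohol dehydrogenase H78_05826 (3.35), the hypothetical gene H78_05825 (3.34) and the transporter subunit H78_02553 (3.19). The calls of all 10 held when any single library was left out.

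Genes of the ped cluster, which encode the oxidation of 2-phenylethanol and other alcohols, made up 5 of the 10 largest falls. The quinoprotein ethanol dehydrogenase gene pedE fell by 4.24 on the log2 scale (SE 0.33, limma adjusted p = 8.47e-05). The pedD gene went from 45.9 ± 24.7 to 3.57 ± 1.40 FPKM (SD, n = 3), pedG from 62.6 ± 27.9 to 7.04 ± 2.42 FPKM, pedI, an aldehyde dehydrogenase, from 123 ± 47.8 to 18.2 ± 3.59 FPKM, and pedF, a cytochrome c, from 108 ± 42.9 to 16.5 ± 5.40 FPKM. The glutamate dehydrogenase gene gdhA was also among the largest falls. It went from 743 ± 131 to 158 ± 24.0 FPKM, and speC, for the ornithine decarboxylase that makes putrescine, from 457 ± 127 to 95.3 ± 22.6 FPKM. The remaining falls were those of lysA_1, a diaminopimelate decarboxylase (log2 change -2.17), the azoreductase H78_03329 (-2.20) and the transport protein H78_00275 (-2.61). The call of H78_00275 was lost without wild-type library 3 (limma adjusted p = 0.115) and without mutant library 2 (0.0993), and those of the other 9 held when any single library was left out.

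**Figure D2:**
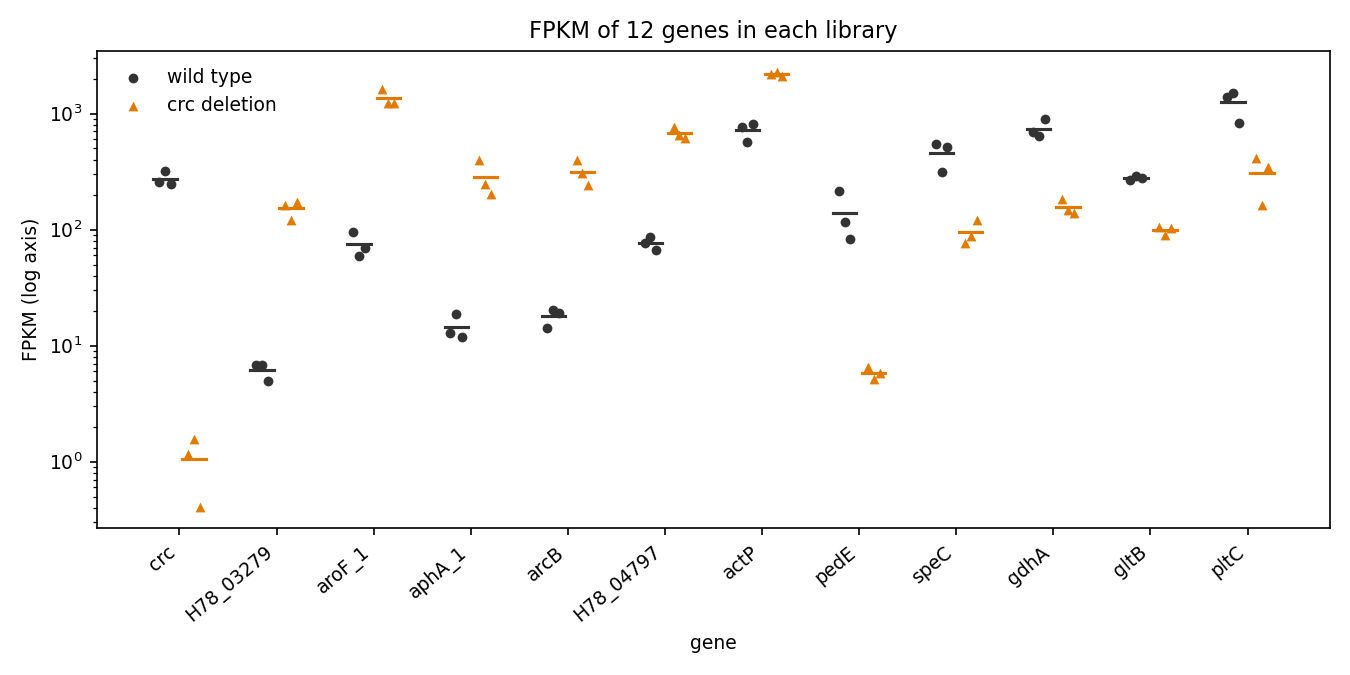
FPKM on a log axis for 12 genes, with 1 symbol per library (circles wild type, triangles crc deletion) and a bar at the mean of 3 libraries. The crc transcript lies between 0.41 and 1.58 FPKM in the mutant. The strains overlap in none of the 12 genes, which follows from picking them among the 262 called genes, none of which overlaps.

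Of 24 measured members of the arginine and proline catabolism list 9 were higher in the mutant, 0 were lower and 15 did not pass, and 15 were higher and 1 lower when adjusted over the list alone. The list was higher by camera (adjusted p = 9.88e-11), and its adjusted p was 0.268 with an estimated correlation. The ast genes encode the succinyltransferase route of arginine breakdown. The astA gene rose from 42.4 ± 7.96 to 212 ± 21.6 FPKM (SD, n = 3) and astA_4 from 37.4 ± 3.00 to 207 ± 16.3 FPKM, with limma adjusted p values of 0.000129 and 6.79e-05. Amino acid and peptide ABC uptake genes, 85 measured, held 13 higher and 1 lower, and 19 higher and 2 lower when adjusted over the list alone (camera adjusted p = 2.82e-08; adjusted p = 0.341 with an estimated correlation). Besides H78_03279, its adjacent permease gene H78_03278 rose from 7.29 ± 0.990 to 57.9 ± 15.4 FPKM and H78_02553 from 25.9 ± 2.55 to 244 ± 7.05 FPKM. Branched-chain amino acid degradation, 16 measured, held 2 higher genes, with 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000248; adjusted p = 0.686 with an estimated correlation). These were mmsA_1, a methylmalonate-semialdehyde dehydrogenase, at 65.3 ± 12.8 and 246 ± 39.3 FPKM, and bkdA1, a subunit of the branched-chain keto acid dehydrogenase, at 146 ± 28.2 and 511 ± 106 FPKM.

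Of 47 measured members of the flagellar list 7 rose and 0 fell, with log2 changes of 0.85 to 1.14, and 11 were higher when adjusted over the list alone. The list median was 0.52, and camera gave an adjusted p of 3.86e-13, with an adjusted p of 0.264 under an estimated correlation. The flgA gene, for P-ring assembly, went from 161 ± 16.8 to 355 ± 38.6 FPKM (SD, n = 3), the regulator gene fleR from 287 ± 67.2 to 592 ± 133 FPKM and the motor switch gene fliM from 208 ± 18.3 to 406 ± 60.5 FPKM. The limma adjusted p of fleR was 0.0439, and its call was lost without any 1 of 5 libraries, while flgA lost its call without mutant library 2 (0.0584) and fliM without 4 of the 6 libraries. Aromatic compound degradation held 3 higher genes of 50 and 9 when adjusted over the list alone. All 3 were phenylacetate-CoA oxygenase genes, with paaG at 7.84 ± 2.96 and 37.3 ± 10.7 FPKM, paaH at 10.8 ± 1.33 and 29.96 ± 5.49 FPKM and paaI at 13.8 ± 1.86 and 36.9 ± 5.12 FPKM. The list passed camera as higher (adjusted p = 0.0333; adjusted p = 0.969 with an estimated correlation), although its median was -0.02 against a mean of 0.17. That call was lost without wild-type library 1 (camera adjusted p = 0.0538), without mutant library 1 (0.173), without wild-type library 2 and mutant library 1 together (0.143) and with the ribosomal protein level as a covariate (0.0941), the last 2 chosen after seeing the data.

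**Figure D3:**
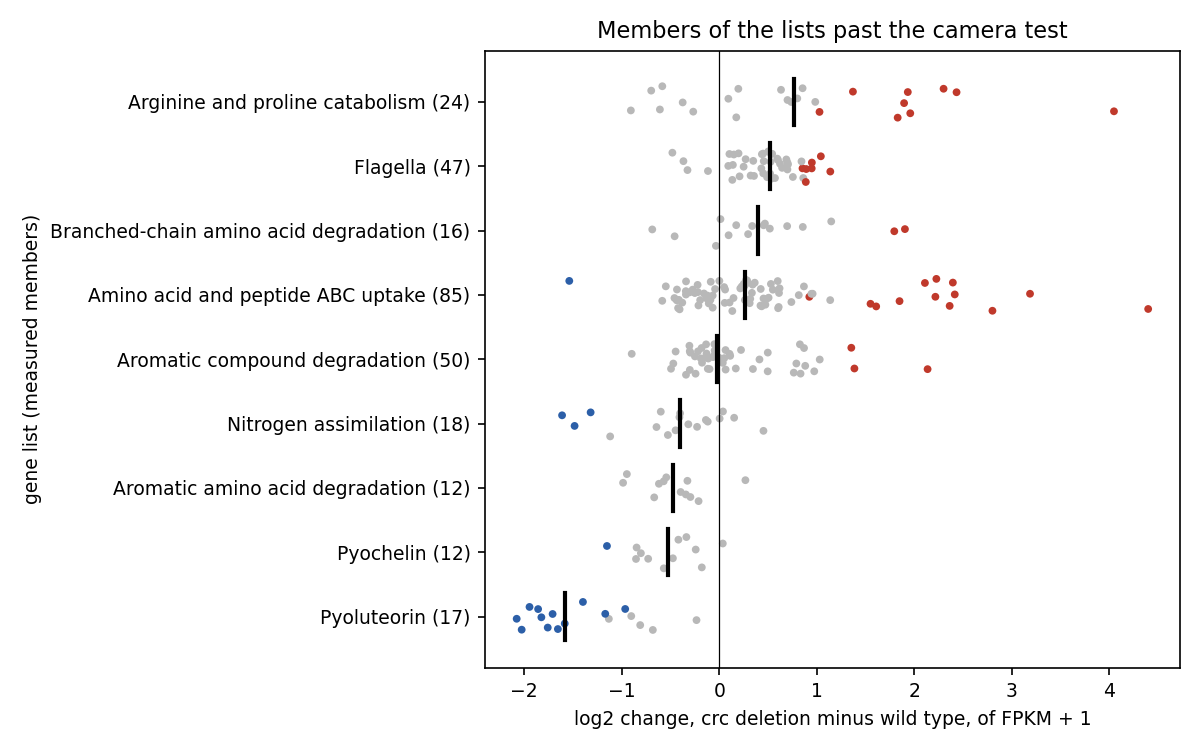
Log2 change of FPKM plus 1 (horizontal axis) of every measured member of the 9 gene lists that passed camera, with the number of members in parentheses and a black bar at the list median. Red members were called higher, blue ones lower and grey ones not called, vertical scatter within a list has no meaning, and the pyoluteorin median lies at -1.58.

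Pyoluteorin genes were lower in the mutant. Pyoluteorin is a chlorinated polyketide antibiotic, and 12 of the 17 measured genes of its list fell, with log2 changes of -2.08 to -0.96, with 0 higher and 5 not passing. Adjusted over the list alone, 16 were lower. The list gave an adjusted p of 3.5e-13 by camera and an adjusted p of 0.341 with an estimated correlation. The polyketide synthase genes pltC and pltB went from 1245 ± 359.7 to 306 ± 129 and from 1231 ± 382 to 310.4 ± 125 FPKM (SD, n = 3), with limma adjusted p values of 0.0105 and 0.0119. The carrier protein gene pltL went from 8494 ± 1546 to 2360.5 ± 1189 FPKM (adjusted p = 0.0195). Without mutant library 2, the limma adjusted p of pltB was 0.0573 and that of pltL 0.138, and without wild-type library 1 that of pltL was 0.0542. Genes of 2,4-diacetylphloroglucinol, another antibiotic, did not pass as a list (camera adjusted p = 0.077), with 1 of 8 lower, and 4 higher and 1 lower when adjusted over the list alone, although the list passed as higher without mutant library 1 or 2. The lower gene was phlG, a hydrolase of the antibiotic, at 293 ± 66.9 and 129 ± 22.4 FPKM, whose call was lost without wild-type library 3 and without mutant library 2. The phlC gene, chosen after its values were seen, stood at 16.4 ± 3.48 and 48.7 ± 26.8 FPKM (limma adjusted p = 0.0558), and it passed without mutant library 1 (0.0339). No gene of the pyrrolnitrin, hydrogen cyanide, orfamide or rhizoxin and Fit toxin lists passed limma. The camera adjusted p was 0.893 for pyrrolnitrin and 0.891 for rhizoxin and Fit toxin, and the 3 hydrogen cyanide and 3 orfamide genes were too few for it. The hcnA gene stood at 405 ± 182 and 381 ± 75.0 FPKM and prnA at 44.2 ± 0.756 and 48.5 ± 2.99 FPKM.

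**Figure D4:**
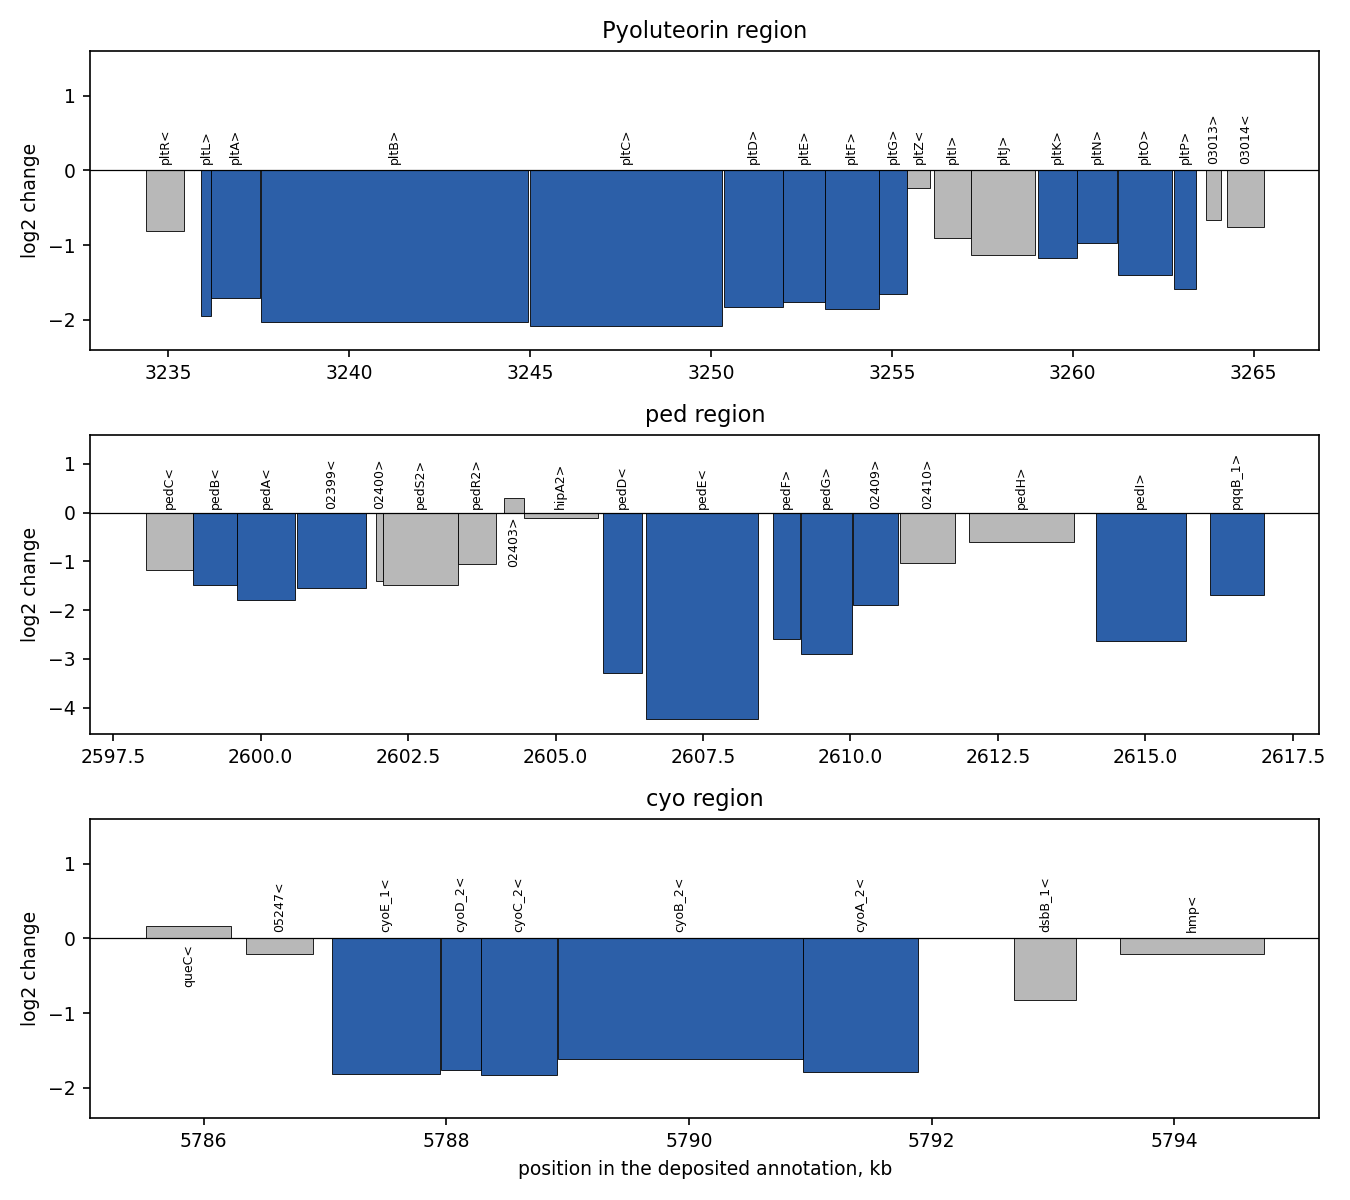
Log2 change (vertical axis) of each gene drawn at its position in kb (horizontal axis, arrowheads give the strand) in the pyoluteorin, ped and cyo regions, blue where called lower and grey where not called. The run of 8 genes from pltL to pltG spans positions 3235905 to 3255424, and the 5 cyo genes span 5787060 to 5791884.

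The list of 18 nitrogen assimilation genes was lower in the mutant by camera (adjusted p = 0.0103, and 0.704 with an estimated correlation). The 3 lower genes were gltB and gltD, the subunits of glutamate synthase, and ureG, a urease accessory gene, and 4 were lower when adjusted over the list alone. The gltB gene went from 279 ± 11.5 to 99.2 ± 8.83 FPKM (SD, n = 3) and gltD from 252 ± 35.3 to 81.2 ± 4.56 FPKM, with limma adjusted p values of 0.000872 and 0.000793. The ureG gene stood at 47.3 ± 5.99 and 18.6 ± 4.62 FPKM and lost its call without wild-type library 3 and without mutant library 2. The list call was lost without wild-type library 3 (camera adjusted p = 0.0508). Outside this list gdhA fell (log2 change -2.22), while the glutamate--ammonia ligase gene H78_04797 rose (3.14). H78_06130, annotated as a glutamine synthetase and chosen after its values were seen, also rose (2.26). It lies between genes annotated as a putrescine aminotransferase and a gamma-glutamyl-gamma-aminobutyrate hydrolase. Whether H78_04797 or H78_06130 serves nitrogen assimilation was not tested. Aromatic amino acid degradation passed camera as lower (adjusted p = 0.00787; adjusted p = 0.704 with an estimated correlation) with 0 of 12 genes past limma and 4 lower when adjusted over the list alone. Its most abundant members were phhB, at 268 ± 15.4 and 211 ± 12.8 FPKM, and hppD, at 166 ± 69.5 and 127 ± 17.7 FPKM, and its call was lost without wild-type library 3 (camera adjusted p = 0.0542). Pyochelin, a siderophore, passed as lower (camera adjusted p = 0.0162; adjusted p = 0.969 with an estimated correlation) with 1 of 12 genes lower, also over the list alone. That gene, pchB, stood at 251 ± 72.3 and 112 ± 28.5 FPKM and lost its call without any 1 of 4 libraries, and the list call was lost without wild-type library 1 (camera adjusted p = 0.0511). In all, camera called 5 lists higher and 4 lower of 38 tested, and with an estimated correlation it called 0.

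Some lists held called genes without passing camera. Among SOS, phage and tailocin genes 10 of 82 were lower (camera adjusted p = 0.0583), with 1 higher and 16 lower when adjusted over the list alone. The pyocin holin gene hol stood at 18.4 ± 6.44 and 4.86 ± 0.984 FPKM (SD, n = 3) and the baseplate gene gpW at 25.5 ± 5.33 and 8.73 ± 1.12 FPKM. Both lost their limma calls without mutant library 2 (0.0584 and 0.0609), and the list passed without any 1 of 4 libraries. Its camera adjusted p was 0.248 without wild-type library 1, 0.782 without mutant library 1 and 0.819 without wild-type library 2 and mutant library 1 together. Of 38 efflux pump genes 6 were lower (camera adjusted p = 0.102), with 1 higher and 7 lower when adjusted over the list alone. Among the lower genes were pedA, at 23.8 ± 9.50 and 5.88 ± 1.59 FPKM, and pltO, at 659 ± 197.2 and 246 ± 50.5 FPKM. Both lie in clusters with lower genes described above, pedA in ped and pltO in plt, so their falls are no separate result. Without mutant library 2 the limma adjusted p was 0.0586 for pedA and 0.105 for pltO, and without mutant library 1 the list passed. Of 32 sugar and polyol genes 3 were higher and 5 lower (camera adjusted p = 0.146), with 11 and 7 when adjusted over the list alone, and the list passed without mutant library 3. The lower ones included the inositol gene iolL, at 51.9 ± 18.05 and 17.8 ± 2.64 FPKM, which lost its call without mutant library 2 or 3. Organic acid uptake held 2 higher genes of 11, both also higher when adjusted over the list alone (camera adjusted p = 0.183). The acetate permease gene actP went from 716 ± 132 to 2182 ± 85.1 FPKM, and the lactate permease gene glcA from 241 ± 11.8 to 467 ± 25.9 FPKM, with its call lost without any 1 of 4 libraries. Of 35 respiratory chain genes 2 were lower, also over the list alone (camera adjusted p = 0.602): cyoD_2, at 681 ± 106 and 200.04 ± 23.8 FPKM, and cyoA_2, at 742 ± 235 and 211 ± 48.3 FPKM, subunits of the cytochrome o oxidase. Histidine utilization held 1 lower gene of 10, hutU, at 44.7 ± 7.09 and 13.8 ± 2.34 FPKM (camera adjusted p = 0.0897), also over the list alone, and the list passed without mutant library 1. Chemotaxis held 1 higher and 1 lower gene of 50 (camera adjusted p = 0.732), with 2 higher and 3 lower when adjusted over the list alone. Exopolysaccharide and adhesion held 1 lower gene of 54, also over the list alone (camera adjusted p = 0.436). The list of the Crc, Cbr and Hfq system had crc as its 1 lower gene of 4 (0.393).

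No gene passed limma in the remaining lists, none of these lists passed camera in the main fit, and except for oxidative stress 0 genes passed when adjusted over the list alone. For central metabolism the camera adjusted p was 0.897 for glucose and Entner-Doudoroff genes, 0.891 for glycerol utilization and 0.436 for the TCA cycle. It was 0.839 for fatty acid and acetate use and 0.839 for polyhydroxyalkanoate. The fatty acid and acetate list does not hold the acetyl-CoA synthetase gene acsA_1, which was called higher and is described below. The glpD gene stood at 5939.6 ± 357 FPKM in wild type and 5971 ± 496 FPKM in the mutant (SD, n = 3), and glpK at 1881 ± 652 and 2876 ± 127 FPKM. The camera adjusted p was 0.839 for denitrification, 0.393 for pyoverdine and 0.625 for other iron uptake. The pvdS gene stood at 45.3 ± 15.3 and 39.7 ± 18.1 FPKM. Gac and Rsm regulators gave 0.328, with rpoS at 1392 ± 451 and 1444 ± 298 FPKM and rsmE at 996 ± 178 and 1436 ± 489.7 FPKM. Type VI secretion gave 0.206, with hcp at 919 ± 159 and 555 ± 118 FPKM, exoenzymes 0.881 and pili 0.452. Ribosomal protein genes gave 0.897, with rpsO, the most abundant transcript, at 53053 ± 11240.0 and 51538 ± 17584 FPKM, and translation factors 0.0701. Heat shock genes gave 0.891, oxidative stress genes 0.124, with 3 lower when adjusted over the list alone and the list past camera without wild-type library 2 and without wild-type library 2 and mutant library 1 together (0.0167), and RNA modification genes 0.956. Ribosomal protein genes passed without wild-type library 2, mutant library 1 or mutant library 3, and in the higher direction without mutant library 1. Translation factors passed without wild-type library 1, wild-type library 3 or mutant library 1, and with the ribosomal protein level as a covariate (camera adjusted p = 0.0159).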

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

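Choices added after seeing the data were median-of-ratios scaling for the called genes (for the lists and crc it had been planned as size factors), quantile normalization, the ribosomal protein covariate, leaving out wild-type library 2 and mutant library 1 together, limma without trend and robust, thresholds on the authors' deposited probability and log2 ratio and symbols matched without copy number. The log2 change of crc stayed between -7.29 and -6.86 when any library was left out and passed limma in every setting. Called genes numbered 131 at an adjusted p of 0.01 (37 lower) and 58 (47 higher, 11 lower) at 0.001 with an absolute log2 change of at least 1, both by construction. Leaving out a library gave 111 to 338 called genes, 85 to 186 higher and 26 to 189 lower. With the ribosomal protein covariate 1162 passed (389 higher, 773 lower) and with both libraries out 828 (368 higher, 460 lower), and the cause was not tested. Of the 262 called genes, 262 and 258 were among these, in the same direction. Median-of-ratios scaling called 324 (201 higher, 123 lower), of which 235 were shared, and quantile normalization 342 (210 higher, 132 lower), of which 247 were shared, against 141 higher and 121 lower in the main fit. The authors' deposited table has 218 genes at a probability of at least 0.8 and an absolute log2 ratio of at least 1. No label states these limits, which were set here. Of the 218 genes, 165 were called by limma. Independent lists would share 9.08, but both lists rest on the same FPKM values, so that number is no benchmark. Deviations of same-numbered libraries correlated at -0.577, -0.237 and 0.097, and no library correlated best with the same-numbered library of the other strain. The main axis of deviation was led by wild-type library 2 (0.612) and mutant library 1 (0.511), which carry different numbers. These correlations therefore cannot tell whether same-numbered libraries shared a day or batch. With the replicate block 367 genes were called, 198 of them lower, and camera called 13 lists. Besides the 9 of the main fit it called the Crc, Cbr and Hfq system, 2,4-diacetylphloroglucinol, SOS, phage and tailocin genes and efflux pumps. Camera called 9 lists, 8 to 13 with a library left out, 0 with an estimated correlation and 5 with fry. The estimated correlations of the 9 lists ran from 0.05 (flagella) to 0.666 (pyochelin), all above the preset 0.01. The camera p-values at the preset thus assume less correlation than was estimated, and a larger correlation raises them by construction. The settings differ in more than that, however. The list of the Crc, Cbr and Hfq system had an estimated correlation of -0.0341, below the preset, yet its unadjusted camera p rose from 0.213 to 0.275. The loss of the list calls therefore cannot be put down to correlation alone, and no other cause was tested. Fry kept 4 of the 9 and lost branched-chain and aromatic amino acid degradation, aromatic compound degradation, pyochelin and nitrogen assimilation. Its other list was that of the Crc, Cbr and Hfq system, which holds the deleted gene. Ribosomal protein genes turned to higher without mutant library 1 (adjusted p = 0.00658), over a range of 0.00601 to 0.804 with a library left out. A set of 74 called genes other than crc joined those the naming rule selects with those chosen after their values were seen. Of these, 49 kept their call without each library in turn. The binding motif search was not run. Depth limits genes near 1 FPKM, which rest on a few fragments.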

Other observations

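Genes of this paragraph were chosen after their values were seen. The aminotransferase gene gabT went from 146 ± 42.6 to 1117 ± 58.7 FPKM (SD, n = 3), a log2 change of 2.97 ± 0.25 (SE) with a limma adjusted p of 9.73e-05, and the succinate-semialdehyde dehydrogenase gene gabD had a log2 change of 1.67 ± 0.24 (SE). Adjacent genes H78_06129, a putrescine aminotransferase, H78_06130, annotated as a glutamine synthetase, and H78_06131, a gamma-glutamyl-gamma-aminobutyrate hydrolase, had log2 changes of 2.01, 2.26 and 2.83. The NAD glutamate dehydrogenase gene H78_02953 went from 105 ± 23.2 to 499.6 ± 36.7 FPKM, opposite to gdhA. The D-amino acid dehydrogenase gene dadA went from 170.4 ± 35.1 to 672 ± 78.3 FPKM and the acetyl-CoA synthetase gene acsA_1 from 1613 ± 76.1 to 4737 ± 679 FPKM, with the call of acsA_1 lost without mutant library 2 (0.0798). The xanthine dehydrogenase gene xdhB stood at 89.1 ± 15.9 and 223 ± 32.0 FPKM and hydA, a dihydropyrimidinase gene, at 19.4 ± 5.61 and 68.0 ± 8.52 FPKM. The cytochrome o oxidase genes cyoB_2, cyoC_2 and cyoE_1, which are not in the respiratory list, had log2 changes of -1.61, -1.83 and -1.81.

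Functional classes of the annotation were tested with Fisher's exact test, two-sided, against all tested genes and adjusted over 23 classes in both directions, a test chosen after seeing the data. Amino acid metabolism held 43 higher genes, where 13.4 were expected (adjusted p = 5.34e-11), and nucleotide metabolism 8 where 2.38 were expected (adjusted p = 0.0382). Secondary metabolism held 15 lower genes where 3.39 were expected (adjusted p = 2.6e-05), 12 of them plt genes. Genes whose class the annotation writes in lower case were not counted in their class. Among them were phlG, which was called lower, and phlC, hcnA and hcnC, which were not called. Neighbouring genes moved together, and 91 called genes lay in 23 runs of at least 3 neighbours on 1 strand called in 1 direction. In 10000 shuffles of the calls the highest number in such runs was 6 (permutation p = 1e-04, the smallest the shuffles can give). The longest run was the 8 genes from pltL to pltG, followed by the 6 from iolB to H78_02803. Genes in 1 operon share a transcript, so these genes and the members of lists are not independent.

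The tests of depth, genomic DNA, the covariate and the splits in the paragraphs that follow were chosen after the results were seen, and that of gene length before. Ribosomal protein genes were lower in wild-type library 2 and mutant library 1 than in the other libraries of their strains, with median log2 differences of -0.65 and -0.82 over 58 genes. The tables argue against sequencing depth, since the estimated depth of wild-type library 2 was 0.972 times the mean of the other wild-type libraries and that of mutant library 1 1.30 times that of the other mutant libraries. They argue against gene length, since 852 other genes of matched length moved by 0.24 and 0.06, and the ratio to the ribosomal change was at most -0.0702. To account for the whole difference, genomic DNA would have to make up 36.1% of wild-type library 2 and 43.3% of mutant library 1. It would then add 51.3 and 61.5 FPKM to every gene, while 44.4% and 52.6% of genes lay below those values, which argues against DNA as the whole cause and does not exclude a smaller share. A difference in growth stage within the sampled density range may account for it, but no density per library was used here and no biological explanation was tested.

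The strain difference itself could have come from ribosomal protein levels that differ between libraries. With that level as a covariate, 262 of the 262 called genes stayed called in the same direction. However, the mean log2 level overlapped between the strains, at 10.02 to 10.62 in wild type and 9.73 to 10.65 in the mutant. The covariate could therefore shift the strain estimates only a little. That overlap, more than the covariate fit, argues against ribosomal protein levels as the source. Of the 10 splits of the 6 libraries into groups of 3, 1 gave 262 or more called genes, the real one, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.1, so these splits are too few to exclude chance at 0.05.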
